A study of Drosophila melanogaster with 3 samples.

How the data were processed

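The data were peak lists from ChIP-seq of whole Drosophila melanogaster embryos, aged 0 to 24 h, that carried a Row protein fused to enhanced green fluorescent protein. Per the labels, the immunoprecipitation was done with an antibody against green fluorescent protein, chromatin was sheared by sonication to a size range of 200 to 800 bp, and coordinates refer to assembly dm6. The 3 samples were labelled as biological replicates 1, 2 and 3 of a single group. Their labels name separate biosamples from the same transgenic strain. The control named in the labels as a possible one was not analysed here. The aligner and the peak caller are not given in the sources used here.

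The deposited files were of 2 kinds, IDR-ranked and IDR-thresholded peak lists, where IDR is the irreproducible discovery rate, the estimated rate of peaks that do not repeat between 2 lists. Each peak had a deposited score, which is a scaled IDR, and a deposited signal value, which is the peak's enrichment as the authors' caller gave it. The ranked lists also held the deposited −log10 of the global IDR. Signal values were used only within a list, to describe, rank, filter or compare its peaks. Each replicate had its own ranked and thresholded list. There were also 4 pairs of lists of the whole series. The intervals copied into the replicate columns of their ranked lists were compared with the replicates' own lists. The conservative list, the main list here, was made from replicates 1 and 2, because 90.2% and 72.0% of its copied peaks were found in those replicates and 1.25% of the second set in replicate 3. Other pairs came from replicates 1 and 3 and from replicates 2 and 3, and the fourth, the pooled list, shared almost no copied interval with any replicate. The smallest −log10 IDR in the deposited conservative list was 2.00, so its threshold was a global IDR of 0.01. Of the main list, 99.8% of the peaks had the same interval, summit and signal value as a peak of the pooled ranked list. Its signal values are therefore those of a pool, and which replicates were pooled is not given in the sources used here. Replicate 3 is for that reason not treated as independent of the main list. The same match held for 99.8% of the peaks of the list of replicates 1 and 3 and 99.5% for replicates 2 and 3. Lists without replicate 1 or 2 therefore differ in the choice of peaks and not in the source of their signal values.

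Read numbers were not used here, so depth is unknown and no interval for it is given. The replicates' lists differ in length, and a longer list can come from deeper sequencing, stronger enrichment or both. The p-values across peaks, genes or windows measure their spread within the list and not the spread between embryos, for which mean and SD over the 3 replicates are given.

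Genes and TSSs were taken from Ensembl release 115 (BDGP6.54, the same assembly as dm6), and the sequence from the RefSeq FASTA of that assembly. All peak ends lay within the lengths of the arms. Analyses used the 7 arms 2L, 2R, 3L, 3R, 4, X and Y, with 13968 protein-coding genes and 19630 TSSs. Of the thresholded peaks, 3 in replicate 2 and 27 in replicate 3 lay on other sequences and were left out. A summit within 500 bp of a protein-coding TSS was a promoter summit, and a gene with such a summit was called bound. A distal summit was over 1000 bp from any protein-coding TSS. Each summit was put into the first matching class of promoter, 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic.

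Overlap, promoter share and classes were tested with 1000 circular shifts along each arm. Gene lists, divergent promoters and motifs at bound promoters were tested with two-sided Fisher's exact tests. Motifs and 7-mers at summits were tested with exact McNemar tests on the window of 100 bp on each side of the summit against a flank 1000 bp away. The flank on 1 side was drawn at random for the test, while the flank shares are means of both sides. Base composition was tested by sign flips and signal values by permutation, with 100000 resamples each. Peaks per arm were tested with exact binomial tests. Families of tests were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The 30 gene lists and 14 motifs were written before the data were examined. The pattern for chorion genes also took Cp190 and Cp110, which encode centrosomal proteins and were removed by name. The cytochrome P450 pattern took Cyp1, which encodes a cyclophilin, and the accessory gland pattern took Acp1, which encodes an adult cuticle protein. These genes were not removed. In lists given by symbol, older symbols were matched through RefSeq synonyms where a single protein-coding gene carries them, and other symbols were left out.

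Genes and peaks are named by a rule fixed before the data were examined. It takes the 10 strongest peaks, the 5 strongest distal peaks, of each list past the threshold up to 4 members with the strongest promoter peak and the first 2 in alphabetical order without one, and row, woc, HP1c, HP1b, Ubqn, the HP1a gene, BEAF-32, Dref, M1BP and Cp190. Genes named outside it were chosen after their values were seen.

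The methods were tested on simulated data. With 1 motif planted at 5% of 10000 random summits, 13 of the 14 motifs were called, all but the run of 8 A or T bases, and no motif was called without planting. The 3 7-mers contained in 1 planted motif were all recovered. With 80% of a list's genes made bound, 27 of 30 lists were called, and with genes bound at random 5 of 100 draws gave a call. The random summits lack the low G+C and the promoter share of the real ones, and genes were drawn independently, without shared promoters. The rates of false calls may therefore not hold for the real lists.

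Alternatives covered the lists of other pairs of replicates, the pooled list, other IDR thresholds, the stronger part of the peaks, promoter windows of 250 and 1000 bp, other TSS sets and gene assignments, and other motif windows and flanks. They had been planned for a main list at a global IDR of 0.05, while the deposited threshold was 0.01. The planned lists at 0.05 were therefore run as written, and the deposited lists of the other pairs at 0.01, a stricter IDR of 0.001, a minimum signal of 20, merging of overlapping peaks, the main list with the absent peaks added, summits outside promoters, the nearest-gene assignment for divergent promoters, the 2000 strongest peaks and lists without paralogs were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.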

Results

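Binding of the protein encoded by row was mapped in whole Drosophila melanogaster embryos collected 0 to 24 h after egg laying. Row (relative of woc) is a zinc-finger protein known as a partner of the chromatin proteins WOC and HP1c. Embryos of a transgenic line that carries Row fused to enhanced green fluorescent protein were used, and chromatin was immunoprecipitated with an antibody against that tag before sequencing (ChIP-seq). There was a single group of 3 biological replicates, so the design holds no comparison between conditions. The questions it poses are where in the genome the tagged protein was enriched, at which genes, and on which sequences. Read depth is unknown, because the files used here hold peaks and no read numbers. The length of each peak list was the only measure related to depth.

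At the authors' reproducibility threshold, replicate 1 listed 10959 peaks, replicate 2 listed 8567 and replicate 3 listed 7635. The lists of all peaks before that threshold held 64663 peaks in replicate 1, 29028 in replicate 2 and 29654 in replicate 3. The conservative list of the series, taken here as the main list, held 10483 peaks with a median width of 436 bp, which together covered 3600 kb. Of these peaks, 6507 (62.1%) overlapped a thresholded peak in all 3 replicates, 1862 in 2, 1411 in 1 and 703 in none. At the same threshold, the ranked list of replicates 1 and 2 held 174 further peaks that the thresholded list lacks. They are called the absent peaks below. Replicates were compared in pairs by the share of the shorter list that overlapped the longer by at least 1 bp. That share was 87.1% for replicates 1 and 2, 91.2% for replicates 1 and 3 and 88.4% for replicates 2 and 3. Circular shifts of the lists along the chromosome arms gave means of 5.16%, 5.19% and 3.94% in the same order (one-sided permutation test, p = 0.001 for each pair, the smallest that 1000 shifts can give).

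The peak with the highest signal value of the main list lay at 2R, 15217517 to 15218204 (assembly dm6), upstream of mRpL41, which encodes a protein of the mitochondrial ribosome, with its summit 141 bp from the transcription start site (TSS). Its signal value, which is the authors' own per-peak value, was 9842. The peak ranked 1 in replicate 2, 2 in replicate 3 and 3 in replicate 1. Next came an intronic peak of Adf1, a transcription factor gene, at 2R, 6662759 to 6663690 (signal 9398, 802 bp from the TSS). A promoter peak of Sox14, which encodes an HMG-box transcription factor, followed at 2R, 23978284 to 23978824 (signal 9134). The fourth was at the promoter of Chro, at 3L, 22878628 to 22879168 (signal 8402), whose product Chromator is a chromodomain protein of interbands and the spindle. The rest of the strongest 10 were promoter peaks nearest to Art3, CenG1A, CG14100, CG18549, px and the Polycomb-group gene ph-p, with signal values from 6485 to 7780. All 10 had a thresholded peak in each of the 3 replicates.

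The 5 strongest peaks over 1000 bp from any protein-coding TSS ranked between 11 and 18 in the main list. The first was intergenic, at 2R, 13035096 to 13035570, 11915 bp from the TSS of CG13323 (signal 6046). Intergenic peaks near tara (3R, 16221967 to 16222729) and the Polycomb-group gene Psc (2R, 12984980 to 12985440) lay 3165 bp and 4212 bp from the nearest TSS. The region of tara also held 12 of the absent peaks. The remaining 2 were intronic, in CG11050 (2L, 6612457 to 6613005) and in CG3726 (X, 5918691 to 5919164). Each of the 5 was listed in all 3 replicates.

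The gene row itself carried a promoter peak at 2R, 15213474 to 15214121, with a signal value of 3931 and rank 61. Its own TSS lay 92 bp from the summit. Among the genes of its known partners, HP1b had a promoter peak of signal 760 and rank 1813, woc one of signal 411 and rank 3732, and Ubqn one of signal 251 and rank 5739. HP1c had none, and the nearest summit was 5090 bp from its TSSs. The gene of HP1a had a promoter peak of signal 694. Promoter peaks were also listed at BEAF-32 (signal 968), Dref (579), M1BP (998) and Cp190 (2301), which encode proteins that bind insulators or core promoters. All of these promoter peaks were present in the 3 replicates. The Ubqn peak was nearer to the TSS of dome, the HP1a peak to that of Ssb-c31a and the M1BP peak to that of CG8202, so these assignments rest on shared promoters.

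Promoters held the largest share of the summits. In the main list, 43.3% of summits (4541 of 10483) lay within 500 bp of a protein-coding TSS, and in the single replicates 47.2% ± 3.71 (SD, n = 3). Shifted summits gave 11.4% (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Of the promoter summits, 84.4% lay upstream of the nearest TSS, with a median position of -94 bp. In all, 5089 of 13968 protein-coding genes (36.4%) had a summit at a promoter, against 35.01% ± 4.57 (SD, n = 3) in the single replicates.

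**Figure D1:**
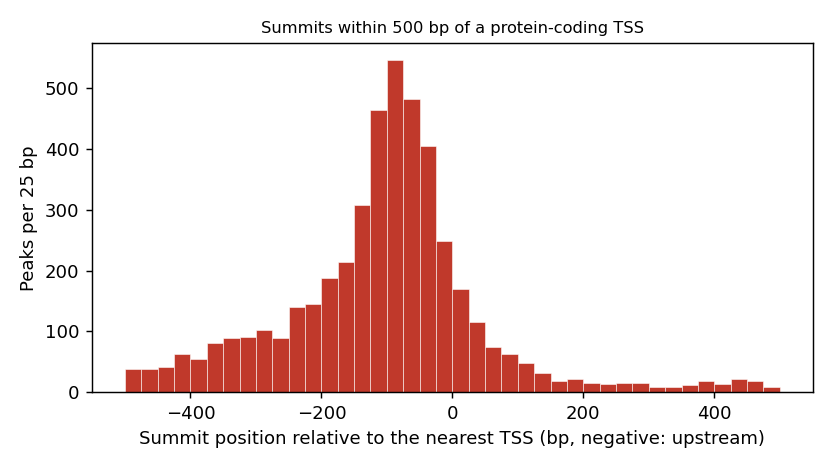
Number of promoter summits of the main list per 25 bp of distance to the nearest protein-coding TSS, with upstream positions negative. Of the 4541 summits, 84.4% lay upstream of the TSS, and the median was -94 bp. Summits between TSSs that point away from each other count as upstream of the nearer one.

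Coding sequence was nearly empty of summits. Only 39 summits (0.372%) lay in coding exons outside promoters, against 13.3% for shifted summits, and 88 (0.839%) lay in 3′ UTRs against 5.22% (two-sided permutation tests, Benjamini-Hochberg adjusted p = 0.0028 for both). Both kept that direction and passed the threshold in all 12 alternatives. Intergenic sequence held 16.2% of summits against 27.8%. Introns held 37.3% against 39.96%, and 5′ UTRs outside promoters 0.429% against 0.803%. These shares fall when the promoter share rises, so they were also taken over the 5942 summits outside promoters, a setting chosen after the data were seen. There, introns were higher, at 65.8% against 45.1% (permutation test, adjusted p = 0.003). Intergenic sequence was 28.6% against 31.3% (adjusted permutation p = 0.0408). This setting is 1 of 12 alternatives, and introns passed as higher in it alone. They passed as lower in 9 others, with adjusted permutation p from 0.00233 to 0.152 over all 12. Intergenic sequence was lower in all 12 (adjusted permutation p from 0.00233 to 0.0408). Outside promoters, coding exons (0.656% against 14.98%) and 3′ UTRs (1.48% against 5.89%) stayed lower. Other exons, which had not passed over all summits (adjusted permutation p = 0.805), were higher there, at 2.73% against 1.79% (adjusted permutation p = 0.003). The 5′ UTR share did not pass the threshold there (adjusted permutation p = 0.132) or at an IDR of 0.05 from replicates 2 and 3 (0.149), and ran from 0.00233 to 0.149 over 12 alternatives. In the single replicates, 0.249% ± 0.0734 of summits lay in coding exons and 34.7% ± 2.33 in introns (SD, n = 3).

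Genes with a divergent neighbour were bound more often. Of 3815 genes with a protein-coding TSS on the other strand within 500 bp upstream, 2519 (66.0%) had a promoter summit. Of the 10153 other genes, 2570 (25.3%) had one, which gives an odds ratio of 5.73 (two-sided Fisher's exact test, with a p-value too small to be represented). In the single replicates the shares were 63.3% ± 6.02 and 24.4% ± 4.05 (SD, n = 3). A summit between 2 close TSSs counts for both genes. When each peak was given only to the gene with the nearest TSS, the odds ratio was 1.95.

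Of the 30 gene lists fixed before the data were examined, 8 had a higher share of bound promoters than all other protein-coding genes and 10 a lower share (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the lists). Genes are not independent replicates, and the test treats them as such. Among genes with no other protein-coding TSS within 500 bp, 9 lists passed the threshold in place of 18. They were the cytosolic ribosomal protein and spliceosome lists, the circadian clock list (adjusted exact p = 0.0462 there, 0.0462 to 1 over 18 alternatives), and, on the lower side, the odorant, gustatory and ionotropic receptor, cytochrome P450, cuticle and accessory gland lists. When each peak was given only to the gene with the nearest TSS, 12 lists passed, and the mitochondrial ribosomal protein, TCA cycle, autophagy, HP1, segmentation and hemocyte lists did not. With the absent peaks added, the same 18 lists passed.

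Cytosolic ribosomal protein genes were the most often bound. Of 92 genes, 77 (83.7%) had a promoter summit (odds ratio 9.08, adjusted exact p = 3.17e-19), and 75.7% ± 4.39 in the single replicates (SD, n = 3). The strongest promoter peaks of that list were those of RpL34b (signal 1902), RpL26 (1665), RpL32 (1651) and RpS20 (1581), while RpL10Aa and RpL13A had none. The RpL13A promoter did hold a summit among the absent peaks. Among mitochondrial ribosomal protein genes, 48 of 73 (65.8%) were bound (odds ratio 3.37, adjusted exact p = 1.84e-06), and 67.1% ± 1.37 in the single replicates. This rests in part on shared promoters. With each peak given to the nearest gene only, the odds ratio was 1.28 (adjusted exact p = 0.467, 1.96e-09 to 0.467 over 18 alternatives). After mRpL41, their strongest peaks were at mRpS10 (7780), mRpS23 (7715) and mRpL23 (3881). The mRpS10 and mRpS23 peaks are those nearest to Art3 and CenG1A. The genes mRpL1 and mRpL12 had no promoter peak.

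Other genes of general cell function followed. Aminoacyl-tRNA synthetase genes were bound in 24 of 33 cases (72.7%, odds ratio 4.67, adjusted exact p = 1.01e-04), among them GluProRS (signal 3062), SerRS (2338), ThrRS (1369) and ProRS-m (1314). AlaRS-m and AsnRS-m had no promoter peak. Spliceosome genes were bound in 19 of 29 cases (65.5%, adjusted exact p = 0.00415), with the strongest peaks at U2af50 (2117), snRNP-U1-C (1375), noi (1002) and SmD1 (845), and no peak at Prp3 and Prp38. Of 20 autophagy genes, 14 were bound (70.0%, adjusted exact p = 0.00813), including Atg18a (2446), Atg9 (2032), Atg4b (1820) and Atg7 (1574) but neither Atg10 nor Atg101. On the TCA cycle list, as written beforehand, 11 of 17 genes were bound (64.7%, adjusted exact p = 0.0358), with peaks at Idh3g (3029), mAcon1 (1810), Pdhb (1779) and Fum1 (1447) and none at Idh and Mdh2. The TCA cycle list passed the threshold in 2 of the 3 replicates. Without replicate 1, the adjusted p of that list was 0.114, and over 18 alternatives it ran from 0.0104 to 0.21.

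The lists of chromatin proteins were also higher. Genes for HP1 and heterochromatin proteins were bound in 16 of 25 cases (64.0%, odds ratio 3.11, adjusted exact p = 0.012), and 61.3% ± 8.33 in the single replicates (SD, n = 3). The list passed the threshold in 2 of the 3 replicates and not in replicate 2 (adjusted exact p = 0.0795), and over 18 alternatives its adjusted p ran from 0.00159 to 0.181. Besides row, HP4 (signal 1449), Su(var)3-7 (899) and HP5 (776) had the strongest promoter peaks, and G9a and HP1c had none, although the G9a promoter held a summit among the absent peaks. Genes for insulator and architectural proteins were bound in 15 of 21 cases (71.4%, odds ratio 4.37, adjusted exact p = 0.00493). They were led by Chro, Cp190, M1BP and Trl, which encodes GAGA factor (signal 985), while CG1910 and Elba1 had no promoter peak. The CG1910 promoter held a summit among the absent peaks. Several of the peaks named for the higher lists were nearer to the TSS of another gene. Those of RpS20, ProRS-m, U2af50, Atg9, Atg4b, Atg7, Su(var)3-7 and HP5 were nearer to CG17271, Snup, PIG-Q, CG7747, Hibch, Sec6, Ravus and Evi5.

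**Figure D2:**
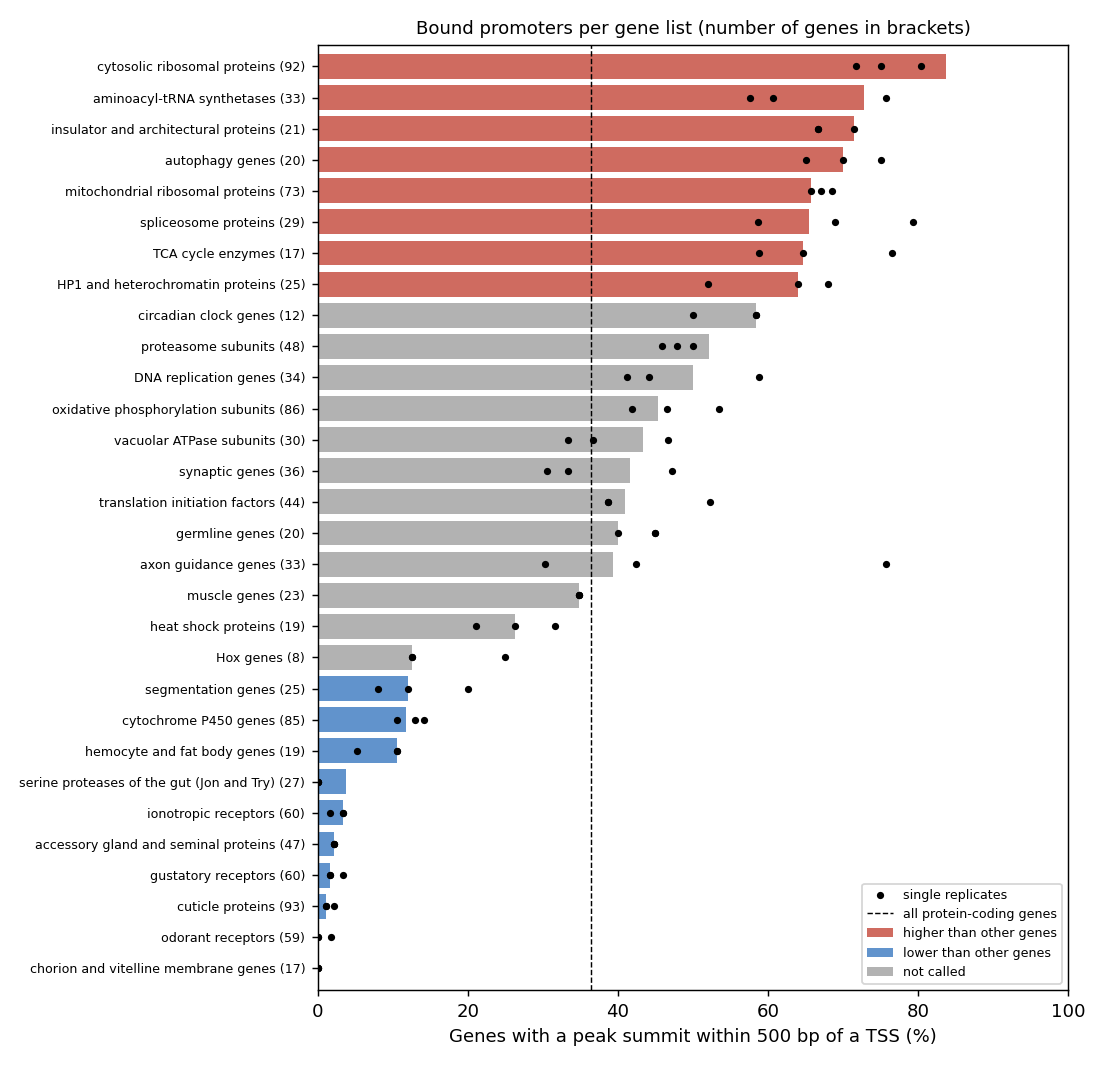
Share of the genes of each of the 30 lists with a summit within 500 bp of a TSS. Bars give the main list, black points the 3 single replicates and the dashed line all protein-coding genes (36.4%). Cytosolic ribosomal protein genes reach 83.7%, and odorant receptor and chorion genes 0%.

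The chemoreceptor, chorion, cuticle, accessory gland, gut protease and cytochrome P450 lists were seldom bound. No promoter summit was found at 59 odorant receptor genes, such as Or10a and Or13a (adjusted exact p = 4.06e-11), or at 17 chorion, vitelline membrane and yolk protein genes, such as Cp15 and Cp16 (adjusted p = 0.00161). Of 93 cuticle protein genes, 1 was bound, Cpr65Ea (signal 249), and Cpr100A and Cpr11A were not (adjusted exact p = 6.01e-16). Single genes were also bound among 60 gustatory receptors (Gr97a, signal 671, adjusted exact p = 6.70e-10), 47 accessory gland and seminal protein genes (Sfp26Ad, 490, adjusted p = 9.42e-08) and 27 gut serine protease genes (Jon65Ai, 127, adjusted p = 4.67e-04). In these 3 lists, Gr10a, Gr10b, Acp1, Acp24A4, Jon25Bi and Jon25Bii were without a peak. Acp1 encodes an adult cuticle protein and is on the accessory gland list only because its symbol matched the pattern. Of 60 ionotropic receptor genes, Ir31a (237) and Ir60b (202) were bound and Ir100a and Ir10a were not (adjusted exact p = 6.80e-09). On the cytochrome P450 list, 10 of 85 genes were bound (11.8%, adjusted exact p = 1.61e-06). The strongest peaks on that list were at Cyp6u1 (2157), Cyp317a1 (869), Cyp1 (590) and Cyp4d1 (516), with none at Cyp12a4 and Cyp12b2. Cyp1 encodes a cyclophilin and not a cytochrome P450, and it is counted among the 10 because its symbol matched the pattern of the list. The peaks counted for Gr97a, Sfp26Ad, Jon65Ai, Ir31a, Ir60b and Cyp6u1 were nearer to the TSS of another gene, namely CG5521, Gpdh1, tant, LSm-4, Letm1 and Ufsp1.

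The segmentation list and the hemocyte and fat body list were also lower, with less support. Of 25 segmentation genes, 3 were bound (12%, odds ratio 0.237, adjusted exact p = 0.021), namely ptc (signal 1456), ci (660) and bcd (234), while Kr and cad were not. Of 19 hemocyte and fat body genes, drpr (549) and vkg (261) were bound (10.5%, adjusted exact p = 0.03), and Col4a1 and Fbp1 were not. Without replicate 2, the adjusted p of the segmentation list was 0.138, and over 18 alternatives it ran from 0.00461 to 0.279. For the hemocyte and fat body list it ran from 0.00704 to 0.391. In the single replicates, the segmentation list passed the threshold in 1 of 3 and the hemocyte and fat body list in 2 of 3.

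The other 12 lists did not pass the threshold. Among them, oxidative phosphorylation subunit genes were bound in 39 of 86 cases (45.3%, adjusted exact p = 0.138) and proteasome subunit genes in 25 of 48 (52.1%, adjusted p = 0.054). Taken alone, replicates 1 and 3 had the oxidative phosphorylation list higher (adjusted exact p = 0.0248 and 0.0141) and replicate 3 the proteasome list (adjusted p = 0.0215), so both are undecided. Without replicate 2, the adjusted p of the oxidative phosphorylation list was 0.0314, and over 18 alternatives it ran from 0.00116 to 0.823. Without paralogs whose symbols end in L, T or R, or in T or R and a number, a setting chosen after the data were seen, 25 of 32 proteasome genes were bound (78.1%, adjusted exact p = 7.52e-06) and 36 of 68 oxidative phosphorylation genes (52.9%, adjusted p = 0.0101). For the proteasome list, the adjusted p over 18 alternatives ran from 7.52e-06 to 0.561. Of 34 DNA replication genes, 17 were bound (adjusted exact p = 0.157). Without replicate 2 that adjusted p was 0.0082, and over 18 alternatives it ran from 0.00249 to 0.815. Of 44 translation initiation factor genes, 18 were bound (adjusted exact p = 0.616, 0.0188 to 0.869 over 18 alternatives). Vacuolar ATPase genes were bound in 13 of 30 cases (adjusted exact p = 0.564), circadian clock genes in 7 of 12 (0.187), synaptic genes in 15 of 36 (0.67) and germline genes in 8 of 20 (0.845). Muscle genes were bound in 8 of 23 cases (adjusted exact p = 1), heat shock protein genes in 5 of 19 (0.572) and Hox genes in 1 of 8 (0.355). Axon guidance genes were bound in 13 of 33 cases in the main list (adjusted exact p = 0.772, 0.0111 to 0.956 over 18 alternatives). In the single lists 25 of these 33 were bound in replicate 1, 10 in replicate 2 and 14 in replicate 3, and the list passed the threshold in replicate 1 alone (adjusted exact p = 1.18e-04).

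Some core promoter sequences were frequent at promoter summits. The DRE, the site of DREF and BEAF-32, was found within 100 bp of 17.2% of promoter summits, against 2.27% of flanking windows 1000 bp away (exact McNemar test, adjusted p = 5.93e-138). In the single replicates the share at promoter summits was 17.3% ± 0.798 (SD, n = 3). Ohler motif 1, the site of M1BP, was found at 4.999% against 0.297%, and Ohler motif 7 at 21.5% against 7.32% (exact McNemar tests, adjusted p = 8.38e-49 and 3.08e-80). Ohler motif 5 (11.2% against 11.0%) and the initiator (16.4% against 16.6%) did not pass the threshold there (adjusted exact p = 0.866 and 0.828). At the 5038 distal summits, DRE was found at 2.30% against 2.29% in the flanks (adjusted exact p = 0.473) and motif 1 at 0.298% against 0.189% (adjusted p = 0.6). Motif 7 was found at 6.35% of distal summits against 5.29% (adjusted exact p = 0.018). Runs of 8 A or T bases were higher at both kinds of summit, at 91.6% against 56.8% for promoters and 91.9% against 77.9% for distal peaks. These tests do not control for base composition.

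**Figure D3:**
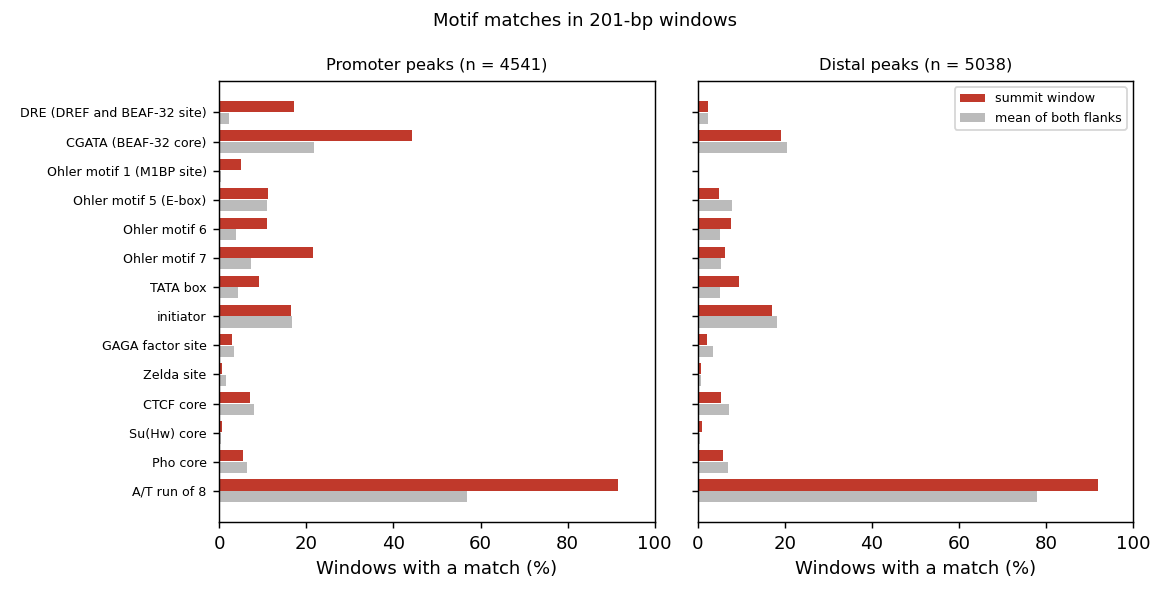
Share of windows of 100 bp on each side with a match to each of 14 motifs, at promoter summits on the left and distal summits on the right. Red bars are summits and grey bars the mean of both flanks. DRE stands out at promoter summits (17.2% against 2.27%) and not at distal ones (2.30% against 2.29%).

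Bound promoters also differed from unbound ones. Within 250 bp of the most 5′ TSS, DRE was found at 28.5% of the 5089 bound genes and 12.9% of the 8879 others (odds ratio 2.68, Fisher's exact test, adjusted p = 1.48e-109). Motif 7 was found at 36.6% and 18.5% (odds ratio 2.54) and motif 1 at 10.8% and 4.04% (odds ratio 2.88). The TATA box and the initiator, elements of regulated promoters, were less frequent at bound genes, at 15.5% against 20.5% and 39.7% against 51.0% (odds ratios 0.711 and 0.633). Around the summits themselves the TATA box was more frequent than in the flanks, at 9.14% against 4.37% for promoter summits and 9.51% against 5.16% for distal ones (exact McNemar tests, adjusted p = 8.06e-18 and 1.12e-15). Its pattern is nearly all A and T, and these tests do not control for composition. Mean G+C was 35.9% at promoter summits against 44.8% in their flanks, and 34.7% against 40.9% for distal ones. In unbound promoters matched on G+C, the odds ratios were 2.32 for DRE, 2.71 for motif 7, 2.68 for motif 1, 0.724 for the TATA box and 0.678 for the initiator. The run of 8 A or T bases, with an odds ratio of 2.46 before matching, did not pass the threshold after it (1.21, Fisher's exact test, adjusted p = 0.206).

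In a search of all 8192 7-mers, joined with their reverse complements, 1742 were higher at summits of the main list than in the flanks and 3664 lower (exact McNemar tests, adjusted over all 7-mers). Of the 20 with the smallest p, 18 consisted of A and T alone, and all 64 such 7-mers were higher. AAAATAT led, at 29.6% of summits against 13.7% of flanks. Of the 7-mers with G or C, ATCGATA, which overlaps the DRE, came first, at 10.2% against 2.57%, followed by CTATCGA (7.14% against 1.51%) and CAGTGTA (6.73% against 1.65%). The 7-mer with the smallest p among the lower ones was CGAGGAG, at 0.601% against 3.74%.

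Summits were poor in G and C. The mean G+C share was 35.4% within 100 bp of the summit and 42.7% in the flanks, a difference of -7.34 percentage points (SD over peaks 11.2, sign-flip permutation test, p = 1e-05, the smallest that 100000 resamples can give). It was lower at the summit in 73.9% of peaks. The difference was -8.85 points at promoter summits and -6.15 points at distal summits. In the single replicates the mean at summits was 35.2% ± 1.07 (SD, n = 3).

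**Figure D4:**
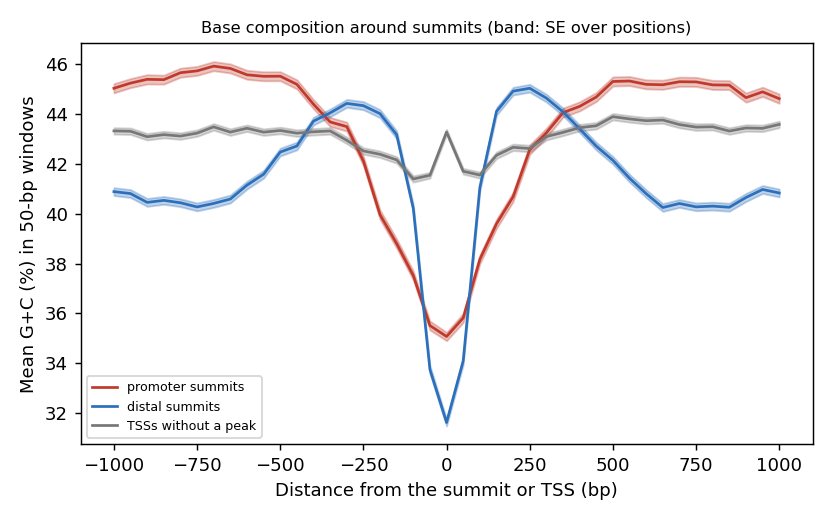
Mean G+C in windows of 50 bp around promoter summits (red), distal summits (blue) and TSSs of genes without a promoter summit (grey), with bands of 1 SE over positions. At the centre the values are 35.1%, 31.6% and 43.3%.

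Promoter peaks had higher signal values than the rest of the main list, with medians of 397 and 229. The mean log2 signal differed by 0.74 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Among promoter peaks, those with a run of 8 A or T bases had higher signal values than those without, with medians of 420 and 236 (log2 difference 0.90, permutation test, adjusted p = 1.4e-04). That difference kept its direction and passed the threshold in all 12 alternatives. Among promoter peaks of the main list, 4 other motifs passed it and 9 did not. Peaks with motif 7 or a TATA box were higher (log2 differences 0.15 and 0.21, adjusted permutation p = 0.0278 for both), and those with DRE or motif 1 lower (-0.16 and -0.33, adjusted permutation p = 0.0278 and 0.0133). These 4 depended on the choice of peaks. In the list without replicate 1, 99.5% of the peaks kept the signal value of the pooled ranked list, so only the choice of peaks changed. Without replicate 1, DRE and motif 1 did not pass (adjusted permutation p = 0.703 and 0.0505). At an IDR of 0.001, motif 7 and the TATA box did not (adjusted permutation p = 0.76 and 0.132). Over all peaks, those with DRE were higher (log2 difference 0.20, adjusted permutation p = 5.60e-04) and those with motif 1 did not pass (0.10, adjusted p = 0.426). Over 12 alternatives the adjusted permutation p ran from 4.67e-05 to 0.812 for DRE, to 0.426 for motif 1 and to 0.859 for motif 7, and from 7.00e-05 to 0.132 for the TATA box.

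The X chromosome carried more peaks for its length than the other arms, with 95.6 peaks per Mb and 2250 peaks, 1.25 times its share of the length (exact binomial test, adjusted p = 6.80e-30). Of its 2196 protein-coding genes, 41.9% were bound, against 35.4% of genes elsewhere (Fisher's exact test, odds ratio 1.32, adjusted p = 5.30e-08). Arm 3R had 71.6 peaks per Mb, 0.939 times its share (exact binomial test, adjusted p = 0.00129). That difference depends on the absent peaks, as 111 of the absent peaks lay on 3R. With them added, the ratio was 0.968 and did not pass the threshold (adjusted exact p = 0.104, 2.28e-05 to 0.104 over 11 alternatives), while 2L (1.05) and 2R (0.952) did. The X was higher in all 11 alternatives (ratio 1.17 to 1.27). On the small chromosome 4, 45 of 80 genes were bound (56.3%, Fisher's exact test, adjusted p = 9.30e-04), while its peak density of 66.0 per Mb did not pass the threshold against its share of the length (adjusted exact p = 0.211, 3.93e-04 to 0.855 over 11 alternatives, 4 of which were lower). No peak of the main list lay on Y, where the copy number in the mix of embryos is not known. In the single replicates the X had 79.8 ± 14.1 peaks per Mb and 3R 62.2 ± 10.9 (SD, n = 3), and the X had the highest density of the 7 arms in each replicate.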

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

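The test of left-out sites was planned before its result was seen. The ranked list of replicates 1 and 2 held 174 peaks at the reproducibility threshold that the thresholded list lacks, a signal in data outside the comparisons above. The strongest lay at 2L, 480581 to 481377, in an intron of ush, with a signal value higher than any peak of the main list. Others lay at Lk6 (signal 6554), larp (5156), tara (4432), pont (3492) and trx (2939), genes chosen after their values were seen. Of the 174, 111 lay on 3R and 44 on 2L, and 53.4% were at promoters.

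A candidate explanation is that the authors left these sites out of all thresholded lists. If so, few of these peaks should overlap a peak of any thresholded list of the series. Of the 174, 0.575% did (1 peak), as that explanation needs. When absent peaks less than 50 kb apart were joined, 42 clusters of several held 156 of them. In 9 clusters, 44 peaks of the main list lay between absent ones, so those stretches were not left out as a whole. Whether sites were removed, and why, is not given in the sources used here, and no biological explanation was tested. Of all protein-coding genes, 84 had a promoter summit among the absent peaks and none in the main list, RpL13A, G9a and CG1910 among them.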

How the results depend on the processing

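The lists without replicates 1 and 2 at the main threshold, the IDR of 0.001, the minimum signal of 20, the merging of overlapping peaks, the 2000 strongest peaks, the addition of the absent peaks, the summits outside promoters, the nearest-gene assignment for divergent promoters and the lists without paralogs were chosen after the data were seen. The promoter share (35.4% to 54.0% over 16 alternatives), the divergent promoters (odds ratio 1.95 to 6.97 over 14), the G+C difference (-8.95 to -6.15 over 13), the signal of promoter peaks (log2 difference 0.53 to 0.86 over 12, and 0.154 as a difference in rank) and the replicate overlaps (73.8% to 88.5% over 4 each) kept their direction and stayed past the threshold. The number of peaks was 5242 in the stronger part and 6950 at an IDR of 0.001, by construction. The intron share was reversed among summits outside promoters (ratio 1.46), and at an IDR of 0.05 from replicates 1 and 2 and after merging of overlapping peaks it did not pass the threshold. At an IDR of 0.05 from replicates 1 and 2, 5 arms passed the threshold in place of 3. The lists at 0.05 were cut from the ranked lists, so that list also holds the absent peaks. With the absent peaks added to the main list, 2L and 2R passed and 3R did not. Among genes that share no promoter, 9 gene lists passed in place of 18, with fewer genes tested. Of the 14 motifs, 9 passed at distal peaks alone and 8 at promoter peaks alone. The BEAF-32 core CGATA was reversed at distal peaks (ratio 0.936) and the GAGA factor site with a window of 250 bp (ratio 1.39). DRE went with lower signal at promoter peaks and was reversed over all peaks (log2 difference 0.20). The number of motifs that went with signal ranged from 3 to 5 without replicate 1 or 2, and was 3 at an IDR of 0.001. For the arms, the motifs and the signal, the cause was not tested. The planned stricter IDR of 0.01 removes no peak and was not run, for the replicate overlap as well. Without replicate 3, the list at the main threshold is the main list itself. Read depth is unknown, so how far depth limits the shorter lists could not be measured. No paired analysis was possible because there was a single group.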

Other observations

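The test of GAGA elements was chosen after the result was seen, as were the comparison with the weakest peaks and the genes named for replicate 1. Axon guidance genes were bound more often in replicate 1 than the main list shows. In that replicate, 25 of 33 had a promoter summit, and 11 of them had one in no other replicate: robo1, robo2, sli, NetA, Fas3, Sema2a, Sema2b, caps, Eph, Ephrin and Wnt5. Replicate 1 also had 2488 peaks (22.7%) found in no other replicate, against 713 (8.33%) in replicate 2 and 284 (3.73%) in replicate 3. Of the 713 peaks of replicate 2 alone, 14.4% lay at promoters.

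Outside protein-coding genes, 184 of 2355 non-coding RNA genes far from a coding TSS had a peak (7.81%), as did 9 of 211 tRNA genes (4.27%). The share was 7.41% for snRNA genes (2 of 27), 3.26% for snoRNA genes (6 of 184) and 0.803% for pseudogenes (2 of 249). These shares were not set against a background share, so they do not show enrichment.

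The extra peaks of replicate 1 may be the same kinds of site, seen to a lower level. DRE at their 1142 promoter summits was 8.44 times as frequent as in the flanks (18.5% against 2.19%), as that explanation needs. That ratio cannot decide, because the flanks lie 1000 bp away and DRE also occurs at unbound promoters (12.9% within 250 bp of the TSS). The promoters of replicate 1 alone were not compared with unbound ones. GAGA elements were 2.67 times as frequent there (7.71% against 2.89%), which argues against it as the whole account, since the ratio at promoter summits of the main list was 0.909. Mean G+C also differed, over all summits of replicate 1. It was 39.7% (flanks 42.5%) for peaks found in no other replicate and 35.2% (flanks 43.1%) for those found in both others. The explanation also needs the higher gene lists to be favoured. At promoter peaks of replicate 1 alone, none of these lists passed the threshold. Their odds ratios ran from 0.424 (HP1) to 2.27 (aminoacyl-tRNA synthetases). This cannot decide, because most genes of these lists were also bound in the other replicates. Only the axon guidance list was higher (odds ratio 6.68, Fisher's exact test, adjusted p = 6.81e-05), and it had not passed in the main list. At the weakest 25% of promoter peaks the GAGA ratio was 2.42 in replicate 1 (6.65% against 2.75%), past the threshold. It was 0.735 in replicate 2 and 1.09 in replicate 3, neither past it. The weakest peaks of replicate 1 are not a separate check, since its peaks found in no other replicate were weak themselves. Their median signal was 55.3, against 160 for its peaks found in both others. The lists of replicates 2 and 3 are shorter, so their weakest 25% may not reach equally weak sites. Weak sites of another kind, a different mix of embryo ages and a difference in depth stay open, and none was tested.

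Low G+C at distal summits may come from the composition of the libraries or from repeats. Of the windows far from coding TSSs with as little G+C as the median distal summit, 12.3% overlapped a peak of the longest ranked list, against 23.9% of other windows, which argues against low G+C alone being enough for a peak. For the main list, the shares went the other way, at 2.65% and 2.35%, and a bias from composition stays open. Of distal summit windows, 5.16% had most bases masked as repeats, and without them G+C was still 35.1% at summits against 40.9% in flanks. No biological explanation was tested.

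The higher gene lists may owe their bound promoters to core promoter motifs or to shared promoters. Within strata of DRE, motif 1 and motif 7, their odds ratio was 3.63 (95% interval 2.81 to 4.70), against 4.71 without strata, which argues against these motifs as the whole cause. Among genes with no other coding TSS within 500 bp it was 5.37 (95% interval 3.75 to 7.68, 131 genes), which argues against shared promoters as the whole cause for the lists as a set, although only 2 of the 8 lists passed the threshold there. The cytosolic ribosomal list weighed heavily, and without it the odds ratio was 3.11 (95% interval 1.98 to 4.88, 76 genes), a check added after the first value was seen. The genes were those of lists already past the threshold, and transcription level was not analysed here.

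The summit of the mRpL41 peak lay 4124 bp from the row TSS and that of the row peak 92 bp, so extra copies of the row region in the transgenic line could raise both. The other 3 peaks within 20 kb had a median signal percentile of 62.0, between the limits set beforehand, and are too few to decide.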
